A study of Rattus norvegicus with 4 samples.

How the data were processed

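Gene expression was measured in Sertoli cells, the somatic cells of the seminiferous tubule that nurse the germ cells, isolated from 20-day-old male Sprague-Dawley rats. Per the labels' protocols, the cells were plated in serum-free medium and kept for 72 h, either without treatment or with cAMP, the second messenger through which follicle-stimulating hormone acts on these cells. The form and dose of cAMP are not given in the sources used here. Total RNA was turned into biotin-labelled cRNA and hybridised to one-colour Affymetrix rat expression arrays. The labels name 2 control and 2 cAMP samples and call them biological replicates. Nothing in the labels says whether the replicates came from separate cell preparations, so the p-values measure the spread between these samples, which may be partly technical.

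The deposited values are probe set intensities on a linear scale, made by the authors with GCOS and MAS5, per the submitters' processing notes. Versions and settings are not given in the sources used here. The mean signal without the lowest and highest 2% of the values was 125 on each of the 4 arrays, so the arrays had been scaled to a common trimmed mean before deposit. Detection calls were not used here. The array holds 31099 probe sets, of which 57 are controls. In the platform annotation used here, 20832 probe sets carry 1 gene symbol, 436 carry several and 9831 carry none. Of the probe sets with 1 symbol, 20764 were matched to a rat RefSeq gene table of assembly GRCr8, which was used only to bring the symbols up to date. No gene was named from a probe set with several symbols, and no coordinates are given because the files name no genome build.

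From these intensities log2(signal + 16) was computed, with 16 as the pseudocount, and no further normalization was applied. A log2 difference on this scale understates the change of dim genes. Probe sets other than controls were tested if their mean over the 4 arrays lay at or above the 40th percentile, a log2 value of 5.10, which left 18625 probe sets and 10035 named genes. Differences between cAMP and control were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, two-sided). P-values were adjusted by the Benjamini-Hochberg method, and 0.05 was the threshold. In this text rose, fell, higher and lower with a count refer to that threshold. Each log2 difference is cAMP minus control and is given ± its standard error, and signals are given as the mean ± SD of the 2 arrays of a group. The number of arrays limits the precision. The highest signal of the 27 Bacillus control probe sets, 14.2, was taken as background. Where every array of a group lay at or below it, the change is given as at least N-fold, the brighter group's geometric mean against the dimmer group's with each value raised to the background. For a gene with several probe sets the one with the highest mean over the 4 arrays was used. Among the 135 changed probe sets of members of the fixed lists, none had another tested probe set of its gene called in the opposite direction by limma.

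Before the data were examined, 17 gene lists were fixed from general knowledge of Sertoli cells and of cAMP, with the basic helix-loop-helix (bHLH) family among them, together with 8 lists of cell type markers. The bHLH list held 113 genes. The rule for named genes was fixed as well. It takes the 12 largest positive and the 12 largest negative log2 differences among genes past the threshold whose cAMP arrays both lie beyond both control arrays. It adds up to 4 members of each list with the smallest p, any member needed to describe a count of 5 or fewer, and all bHLH members past the threshold over the list alone, up to 20. Any other gene named was chosen after its values were seen: these are the further members given beside a list's count, the members of 3 lists written later, and markers of other cell types. Lists with 5 or more tested members, 20 in all, were tested with camera from limma at its preset inter-gene correlation of 0.01, which asks whether a list shifted relative to the other genes, with adjustment over the lists. Camera with an estimated correlation and fry were the alternatives. With 2 arrays per group the first has few residual degrees of freedom, so a list it did not call is not thereby shown to be unshifted. Its adjusted p was tied at 0.742 for many lists, so that value is not a list's own result. Fry's directional p tests whether a list's genes move, on balance, one way, without comparing them with other genes. Fisher's exact test of the share of changed genes inside against outside each list (two-sided, adjusted over the 20 lists) was chosen after the data had been seen. It counts genes as independent, which members of a list need not be, so its p does not measure the spread between samples.

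On 20 simulated data sets of 18625 probe sets with the means and spreads of the comparison of cAMP with control, 74.9% of 2-fold and 99.9% of 4-fold changes among 200 were recovered. Of the calls, 9.51% were false against a nominal 5%, and with no change simulated a mean of 0.65 probe sets was called. Each simulated data set held 200 changed probe sets, while 2549 were called in the comparison itself. The adjusted threshold depends on that share, so recovery and the false share may differ there. A list shifted by 0.5 on the log2 scale was found by camera in 100% of these data sets, and 2.75% of unshifted lists had p under 0.05. Each probe set was simulated independently and the lists were drawn at random. These rates therefore do not cover lists whose genes move together, such as the interferon list, with an estimated correlation of 0.91. Alternatives were other pseudocounts (1 and 64), no filter and a filter at the 60th percentile, quantile normalization, centring on the median, eBayes without the trend or in its robust form, a 2-fold minimum, each array left out in turn, and the replicate number as a block. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.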

Results

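Sertoli cells of 20-day-old rats were profiled after 72 h in culture with or without cAMP, on 2 arrays per group. The series is about the bHLH family of transcription factors in cell differentiation, and its single comparison asks which transcripts differ between cAMP-treated and untreated cells. The median signal was 32.9 and 33.7 on the control arrays and 31.3 and 33.7 on the cAMP arrays, and between 64.3% and 66.4% of the probe sets lay above background. Across genes, which are not independent replicates, log2 signals of the tested probe sets correlated with r = 0.967 between the control arrays, 0.984 between the cAMP arrays, and 0.895 to 0.925 between arrays of different groups. Control replicate 1 correlated with the cAMP arrays at 0.925 and 0.924, and control replicate 2, which stood further from them, at 0.895 and 0.900. The median SD of a probe set was 0.166 in the control pair and 0.111 in the cAMP pair, on the log2 scale. The ratio of 3' to 5' actin signal, a measure of RNA integrity, was 1.80 and 2.25 on control replicates 1 and 2, and 1.86 and 1.65 on the cAMP arrays. The same ratio for Gapdh was 0.966 and 0.903 on control replicates 1 and 2, and 0.930 and 0.937 on the cAMP arrays. It was lowest on control replicate 2, where the actin ratio was highest.

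The genes most raised by cAMP included Star, Scarb1 and a pair of phosphodiesterases. The signal of Star, which carries cholesterol into the mitochondrion, rose from 65.0 ± 22.7 to 3111 ± 365 (mean ± SD, n = 2 arrays per group), a log2 difference of 5.30 ± 0.21. Scarb1, the receptor for high-density lipoprotein, rose from 65.0 ± 16.1 to 1976 ± 206 (4.63 ± 0.18). The phosphodiesterases Pde10a and Pde4d rose by 4.84 ± 0.20 and 4.70 ± 0.17 on the log2 scale, Pde4d from 28.1 ± 5.87 to 1124 ± 25.6. The cell surface glycoprotein Cd24 lay at background on both control arrays, at 2.9 and 9.4, and reached 1222 and 1449 with cAMP, at least 93.7-fold higher. The ferritin receptor Scara5 was at least 63.7-fold higher, again from background on both control arrays. Dct, an enzyme of melanin synthesis, rose from 16.6 ± 3.89 to 1799 ± 289 (5.80 ± 0.18), and the neurofilament heavy chain gene Nefh rose from 24.1 ± 5.45 to 944 ± 55.6 (4.59 ± 0.17). Wfdc1 (4.31 ± 0.20), the complement protease gene C1s (4.30 ± 0.41), the small proteoglycan gene Dcn (4.17 ± 0.30) and Alas2, the erythroid form of the first enzyme of haem synthesis (4.08 ± 0.22), completed the 12 largest increases. The 2 cAMP arrays differed most for C1s, at 842.1 and 1790. For Dct, Pde10a and Dcn 1 of the 2 control arrays lay at or below background, so the size of their change is uncertain. The adjusted p of these 12 genes by limma ranged from 2.48e-05 for Cd24 to 0.000845 for C1s.

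The genes most lowered by cAMP were led by Igfbp3. Igfbp3, which binds insulin-like growth factors, fell from 888 ± 130.2 to 14.2 ± 3.25, a log2 difference of -4.90 ± 0.19. The secreted glycoprotein gene Stc1 fell from 686 ± 15.7 to 16.4 ± 3.82 (-4.44 ± 0.18), and Ccn2, which encodes connective tissue growth factor, fell from 2058 ± 410.1 to 110.4 ± 17.8 (-4.03 ± 0.19). Tagln, an actin-binding protein of smooth muscle, went from 344.5 and 264.3 on the control arrays to background with cAMP, at least 21.2-fold lower. Myoz2, a protein of the muscle Z-disc, had a log2 difference of -4.02 ± 0.36 and lay at 18.2 and 1.5 on the cAMP arrays. The peptide hormone gene Adm (-3.96 ± 0.26) and the heparin-binding growth factor gene Ptn (-3.69 ± 0.26) fell as well. The remaining genes of the 12 largest decreases were Ddit4l (-3.55 ± 0.22), the organic anion transporter gene Slco1a4 (-3.51 ± 0.19), Dsel (-3.36 ± 0.24), the fatty acid binding protein gene Fabp3 (-3.33 ± 0.18) and the basement membrane gene Nid2 (-3.19 ± 0.27). For Igfbp3, Stc1, Myoz2 and Adm 1 of the 2 cAMP arrays lay at or below background, so the size of their change is uncertain as well. All 24 genes stayed past the threshold when any 1 of the 4 arrays was left out, with the adjusted p by limma at most 0.00579.

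**Figure D1:**
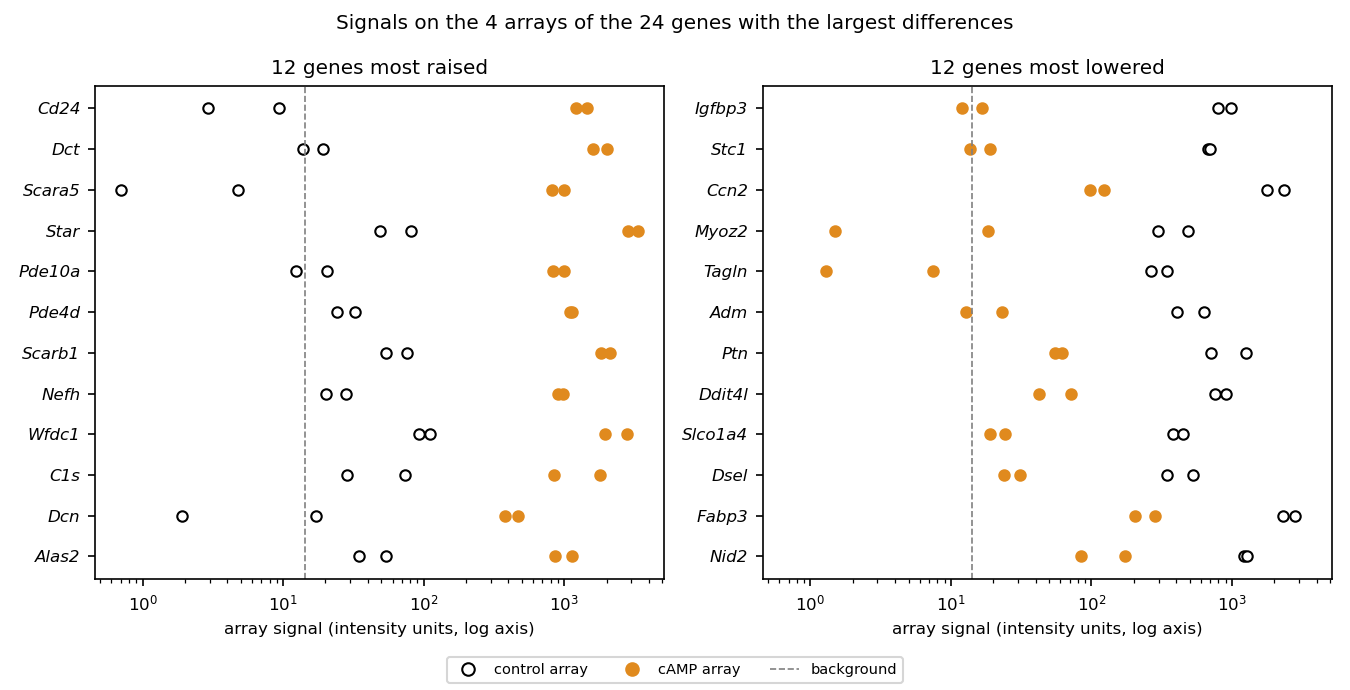
Signal on each of the 4 arrays (log axis, intensity units) of the 12 genes with the largest increase and the 12 with the largest decrease with cAMP; open circles are control arrays, filled circles cAMP arrays, and the dashed line is background at 14.2. For each gene both cAMP arrays lie beyond both control arrays; Star is at 81 and 48.9 without and 3369 and 2852 with cAMP.

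Of the 18625 probe sets tested, 1358 were higher and 1191 lower with cAMP. On the log2(signal + 16) scale, 778 and 583 of these differed by at least 2-fold. They stood for 830 named genes that were higher and 716 that were lower, 15.4% of the genes tested, while 588 changed probe sets had no single gene symbol. The counts depended on the arrays used: without cAMP replicate 1 they were 396 and 314, without cAMP replicate 2 414 and 351, and without control replicate 1 2467 and 2381. Without the filter on dim probe sets 873 were higher and 725 lower.

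Among the bHLH genes, Id4, an inhibitory member that lacks a DNA-binding region, had the largest difference and rose from 150.4 ± 11.2 to 1849 ± 104 (3.49 ± 0.14, adjusted p by limma = 2.90e-05). All 3 other tested probe sets of Id4 were higher too, as was the 1 other of Epas1, while the 1 other of Srebf1 and of Tcf4 did not pass. Epas1, which encodes the hypoxia-inducible factor HIF-2alpha, rose from 1847 ± 237 to 4309 ± 75.6 (1.22 ± 0.13), and Bhlhe41, a repressor in the circadian clock, fell from 126 ± 45.8 to 21.0 ± 5.09 (-1.91 ± 0.27). The related Bhlhe40 rose by 1.34 ± 0.25, opposite to Bhlhe41. Npas2 (1.71 ± 0.29) and Bmal1 (0.75 ± 0.18), partners in the clock's activating complex, also rose, as did the lipid regulator gene Srebf1 (1.12 ± 0.18), Mycl (0.82 ± 0.17) and Hif1a (0.48 ± 0.12). Npas2 lay at 10 and 27.7 on the control arrays, the first below background, so the size of its change is uncertain. Tcf4, an E-protein, fell from 789 ± 248 to 342 ± 65.1 (-1.14 ± 0.23). Of the 113 genes on the list, 47 were tested, 45 lay below the filter and 21 had no probe set named for them here. Of the 47, 8 were higher, 2 lower and 37 did not pass; adjusted over the list alone, 8 were higher and 4 lower, with Tfap4 (-0.83 ± 0.23) and Scx (-0.51 ± 0.15) added. The other Id genes did not pass, with log2 differences of 0.32 ± 0.20 for Id1, 0.05 ± 0.24 for Id2 and 0.16 ± 0.25 for Id3, nor did Hes1 (0.30 ± 0.16), Myc (-0.23 ± 0.44) or Mitf (0.54 ± 0.19). The share of changed genes, 10 of 47 against 1536 of 9988 other genes, did not pass Fisher's exact test (two-sided p = 0.308), and camera gave no shift of the family (adjusted p = 0.333). When cAMP replicate 1 was left out, Id4, Epas1, Bhlhe41 and Bhlhe40 still passed, and when cAMP replicate 2 was left out, Id4, Epas1, Bhlhe41 and Npas2, 4 genes in each case. Tfap4 and Scx passed without control replicate 1, which gave 8 higher and 5 lower, Mitf and Myc without control replicate 2, and without the filter on dim probe sets 6 genes passed, Bhlhe40, Tcf4, Bmal1 and Hif1a being lost.

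**Figure D2:**
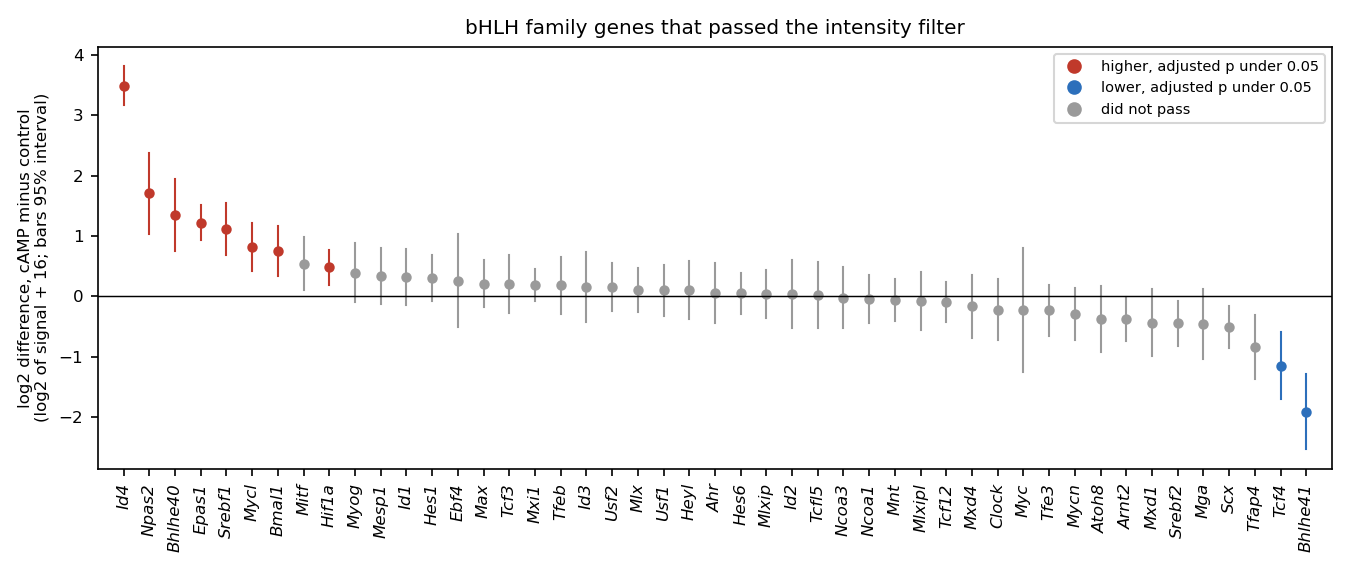
Log2 difference between cAMP and control, on the log2(signal + 16) scale, of the 47 bHLH family genes tested, ordered by size; bars are 95% intervals from limma with 2 arrays per group, and colours show the direction of those past an adjusted p of 0.05. Id4 stands at 3.49 and Bhlhe41 at -1.91, and 37 genes did not pass.

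A further list joined targets of the transcription factor CREB, which protein kinase A activates, with immediate-early genes. Of its 30 tested members 17 rose, 2 fell and 11 did not pass (19 and 2 adjusted over the list alone). Camera called the list higher (adjusted p = 3.10e-09, and adjusted p = 0.742 with an estimated correlation), with a median log2 difference of 1.09 (0.66 with a pseudocount of 64). The nuclear receptor genes Nr4a3 and Nr4a1 rose from 22.4 ± 5.51 to 550.2 ± 47.3 (3.89 ± 0.19) and from 64.6 ± 1.41 to 544 ± 14.2 (2.80 ± 0.15), and the phosphodiesterase gene Pde4b rose by 2.88 ± 0.17. Among other immediate-early genes, Junb (2.49 ± 0.21), Fos (1.86 ± 0.16) and Sik1 (1.96 ± 0.17) rose as well. The 2 that fell were the kinase anchor gene Akap12 (-1.72 ± 0.14) and Egr1 (-1.33 ± 0.19). The list counted 11 higher and 1 lower without cAMP replicate 1, with Egr1 among those lost. Of 36 tested components of the cAMP pathway itself, 5 were higher and 4 lower (6 and 5 adjusted over the list alone). The higher ones were Pde10a, Pde4d, Pde4b, Pde8a (1.52 ± 0.16) and the regulatory subunit gene Prkar2b (1.05 ± 0.25). The lower ones were Akap12, the kinase inhibitor gene Pkig (-0.96 ± 0.14), Akap1 (-0.77 ± 0.18) and Crebbp (-0.59 ± 0.15). Gnas (-0.06 ± 0.11) and Prkaca (-0.20 ± 0.17) did not pass. Pkig, Akap1 and Crebbp were lost without cAMP replicate 1 and also without cAMP replicate 2, which left 1 lower gene in each case; Prkar2b was lost in the first case and Crebbp also without control replicate 2. Without control replicate 1, 7 components were higher and 7 lower. Camera found no shift of the list (adjusted p = 0.577).

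Steroid synthesis genes rose in part. Of 13 tested, 5 rose and 8 did not pass (6 higher adjusted over the list alone). Beside Star and Scarb1 these were the electron carrier gene Fdx1, from 804 ± 44.4 to 3061 ± 196 (1.91 ± 0.12), Por (1.95 ± 0.21) and the mitochondrial translocator gene Tspo (1.29 ± 0.18). Cyp11a1, whose enzyme cleaves the cholesterol side chain, did not pass (0.12 ± 0.20). Nor did Hsd17b1 (-0.43 ± 0.27) and Hsd17b7 (-0.32 ± 0.19), while Cyp17a1, Cyp19a1, Hsd3b1 and Hsd17b3 lay below the filter. No tested gene of a steroid-forming enzyme was thus among the 5 that rose. The list's median was 0.35 (camera adjusted p = 0.00307, and adjusted p = 0.742 with an estimated correlation), and Tspo was lost without cAMP replicate 2. Of 19 genes of cholesterol synthesis and uptake, 2 were lower, Pmvk (-0.89 ± 0.16) and Fdft1 (-0.91 ± 0.19), and 2 higher, Stard4 (1.10 ± 0.26) and Acat2 (0.66 ± 0.17), against 3 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.638). All 4 calls were lost without cAMP replicate 1, without cAMP replicate 2 as well, and Acat2 also without control replicate 2.

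Of 25 tested genes of the actin cytoskeleton and targets of serum response factor, 10 fell, 1 rose and 14 did not pass (11 lower and 1 higher adjusted over the list alone). Camera called the list lower (adjusted p = 0.000149, and adjusted p = 0.742 with an estimated correlation), with a median of -0.37. Ccn2 and Tagln led the list. Tagln is also a marker of peritubular myoid cells on the list fixed for them, where Synpo2 (-1.14 ± 0.29) fell too and Des (1.15 ± 0.20) rose, both lost without cAMP replicate 1 and also without cAMP replicate 2. Fhl2, a LIM domain cofactor, fell from 179.6 ± 1.63 to 27.0 ± 0.424 (-2.19 ± 0.18), vinculin (Vcl) from 3644 ± 361 to 1662 ± 116 (-1.12 ± 0.12) and tropomyosin 1 (Tpm1) from 1309 ± 18.2 to 628 ± 23.6 (-1.04 ± 0.12). Srf itself fell (-0.64 ± 0.15), while Tagln2 rose by 1.06 ± 0.19. The actin gene Acta2 did not pass (-0.19 ± 0.26). Leaving out cAMP replicate 1 left 7 lower genes and leaving out cAMP replicate 2 left 6, with Srf and Tagln2 lost in both cases; without control replicate 1, 3 were higher and 8 lower. The list's median was -0.14 without control replicate 1 and -0.65 without control replicate 2. Of 25 genes of the junctions between Sertoli cells, 9 were lower, 5 higher and 11 did not pass (11 lower and 5 higher adjusted over the list alone). Beside Vcl the lower ones with the smallest p were N-cadherin (Cdh2), from 725 ± 69.6 to 306 ± 2.90 (-1.20 ± 0.14), occludin (Ocln), from 612 ± 75.2 to 233 ± 38.6 (-1.34 ± 0.17), and plakoglobin (Jup, -1.05 ± 0.15). The 5 higher ones were Dsg2 (0.96 ± 0.15), Cldn4, Pard3 (0.81 ± 0.19), the scaffold gene Tjp1 (0.57 ± 0.13) and Ctnna1 (0.47 ± 0.11). Cldn4, at least 2.83-fold higher, lay at background without cAMP. Changed genes made up 14 of the 25 against 1532 of 10010 others (Fisher's exact test, adjusted p = 2.22e-05), while camera found no shift one way (adjusted p = 0.156). Of these junction genes Vcl, Cdh2 and Ocln passed when cAMP replicate 1 was left out, 3 lower and 0 higher by limma, and with Cdh3 4 lower and 0 higher when cAMP replicate 2 was; Cldn4 was lost without control replicate 2 as well.

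Extracellular matrix genes changed in both directions. Of 26 tested, 9 were higher, 6 lower and 11 did not pass (10 and 8 adjusted over the list alone). Within the laminins, Lama5 was at least 16.4-fold higher, from background on both control arrays to 282.8 and 192.3, and Lamb2 (1.06 ± 0.18) and Lama4 (1.07 ± 0.19) rose, while Lama1 (-1.59 ± 0.17) and Lamb1 (-1.78 ± 0.24) fell. Collagen XVIII (Col18a1) rose from 308 ± 85.1 to 1896 ± 103 (2.59 ± 0.19), and the collagen cross-linking enzyme gene Lox rose by 2.10 ± 0.20. The nidogens, which link laminin and collagen IV, both fell, Nid1 from 430.2 ± 149.6 to 89.0 ± 8.20 (-2.05 ± 0.24) and Nid2 as given above. Changed genes were 15 of 26 against 1531 of 10009 others (Fisher's exact test, adjusted p = 8.75e-06). Camera found no shift of the list one way (adjusted p = 0.652). The counts were 5 higher and 4 lower without cAMP replicate 1, and 6 and 4 without cAMP replicate 2, with Lamb2 and Lama4 lost in both cases. Among 18 proteases and their inhibitors 4 were higher and 3 lower (7 and 6 adjusted over the list alone; camera adjusted p = 0.333). Timp1, an inhibitor of matrix metalloproteases, rose from 515 ± 143 to 3437 ± 596 (2.72 ± 0.21). The plasminogen activators moved apart: tissue-type Plat rose from 162 ± 80.8 to 1007 ± 59.5 (2.60 ± 0.29) and urokinase-type Plau fell from 365 ± 56.1 to 97.4 ± 35.2 (-1.77 ± 0.24). The urokinase receptor gene Plaur was at least 5.15-fold higher and the inhibitor gene Serpine2 at least 3.75-fold lower, each at background in the dimmer group, and Ctsk (0.89 ± 0.16) rose while A2m (-0.91 ± 0.24) fell. Timp1, Plat and Plau passed with any 1 array left out. Ctsk and A2m were lost without cAMP replicate 1, as were Plaur and Serpine2, which left 2 higher and 1 lower; Ctsk and A2m were also lost without cAMP replicate 2, which left 3 and 2, and without control replicate 1 the counts were 7 and 2, with A2m lost.

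Products and regulators of Sertoli cells also changed both ways. Of 23 tested, 6 were higher and 4 lower (6 and 5 adjusted over the list alone), a share of changed genes above that of other genes (Fisher's exact test, adjusted p = 0.00406), with no shift one way (camera adjusted p = 0.471). The inhibin alpha subunit gene Inha rose from 1097 ± 206 to 4539 ± 274 (2.04 ± 0.15), while the activin subunit gene Inhba fell from 104 ± 25.2 to 20.6 ± 1.41 (-1.69 ± 0.22). Fabp5 (1.26 ± 0.12) and Plat rose, Dhh (0.74 ± 0.14), Kitlg (0.58 ± 0.14) and Shbg, which encodes androgen-binding protein (0.69 ± 0.18), completed the higher genes, and Gata4 (-0.94 ± 0.12), Aard (-0.51 ± 0.13) and Jag1 (-0.82 ± 0.21) the lower ones. Only Inha, Fabp5, Plat and Inhba passed when cAMP replicate 1 or cAMP replicate 2 was left out, 3 higher and 1 lower in each case; Aard and Shbg were also lost without control replicate 2, and Jag1 without control replicate 1. Of the 9 tested markers of Sertoli cells, 3 of these were higher and 2 lower (4 and 2 adjusted over the list alone; camera adjusted p = 0.486), and when either cAMP array was left out Inha alone passed. The markers Clu (-0.18 ± 0.10), Wt1 (0.21 ± 0.13) and Cldn11 (-0.14 ± 0.11) did not pass, at signals between 1452 and 7278 on the 4 arrays.

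Of 18 tested genes of endoplasmic reticulum stress and heat shock, 10 rose and 8 did not pass (13 higher adjusted over the list alone). Camera called the list higher (adjusted p = 4.57e-07, and adjusted p = 0.742 with an estimated correlation), with a median of 0.77. Asparagine synthetase (Asns) rose from 648 ± 243 to 4738 ± 41.0 (2.89 ± 0.23) and the pseudokinase gene Trib3 from 29.2 ± 5.73 to 186 ± 27.3 (2.16 ± 0.20). The transcription factor gene Xbp1 (1.27 ± 0.16), the chaperone genes Hsp90b1 (1.00 ± 0.14) and Hspa5 (0.84 ± 0.14), and Atf4 (0.70 ± 0.14) rose as well. Calr, Chac1, Ddit3 and Sesn2 were the rest of the 10. None of the list's cytosolic heat shock genes, such as Hspa1a, Hspa8, Hsph1 and Dnajb1, was among the 10. Of the 18 genes, 14 were lowest on control replicate 2, and without that array 10 were higher and 1 lower, with a median of 0.66. When cAMP replicate 1 was left out 5 rose, and when cAMP replicate 2 was left out 4; Hspa5 and Atf4 were lost in both cases and Hsp90b1 in the latter.

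In glycolysis and lactate production, which Sertoli cells run to feed germ cells, 5 of 22 tested genes rose and 2 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.275). Pgk1 (1.15 ± 0.15), Tpi1 (1.38 ± 0.20), Pgam1 (0.55 ± 0.14), Pfkfb3 (0.81 ± 0.21) and the lactate dehydrogenase gene Ldha (0.53 ± 0.13) rose. The pyruvate dehydrogenase kinase genes Pdk1 (-0.74 ± 0.19) and Pdk4 fell, Pdk4 at least 2.81-fold to background. Leaving out cAMP replicate 1 left Tpi1 and leaving out cAMP replicate 2 left Pgk1, 1 higher gene in each case. Pdk1 was lost without control replicate 1 and also without control replicate 2, and Pfkfb3 without control replicate 1, where 7 genes were higher and 1 lower and camera called the list higher. The median of the list was 0.15 over all arrays, 0.30 without control replicate 1 and 0.09, with 5 genes higher and 1 lower, without control replicate 2, on which 15 of the 22 genes were lowest. Of 13 retinoid genes, Rdh10, which starts retinoic acid synthesis, rose from 62.5 ± 9.69 to 332 ± 46.2 (2.14 ± 0.19), and Aldh1a3 rose by 1.38 ± 0.23. The retinoic acid hydroxylase gene Cyp26b1 (-1.18 ± 0.19), Aldh1a1 (-0.85 ± 0.16) and Rbp4 (-1.21 ± 0.27) fell (2 higher and 3 lower over all genes and adjusted over the list alone; camera adjusted p = 0.471). Cyp26b1 and Rbp4 were lost when either cAMP array was left out, Aldh1a1 without cAMP replicate 1, Aldh1a3 without cAMP replicate 2, and Rbp4 also without control replicate 2. Of 17 clock genes 5 were higher and 3 lower, with the same counts adjusted over the list alone, a share above that of other genes (Fisher's exact test, adjusted p = 0.00587; camera adjusted p = 0.638). Beside the 4 bHLH members these were Per2 (1.29 ± 0.16) and Nfil3 (0.75 ± 0.16), which rose, and Nr1d2 (from 1627 ± 239.7 to 799.6 ± 3.68) and Hlf (-1.64 ± 0.27), which fell. The clock list counted 1 higher and 2 lower without cAMP replicate 1, and 2 and 1 without cAMP replicate 2; Per2 was lost in the first, Hlf in the second, and Nr1d2 and Nfil3 in both. Of 26 genes of Wnt, Notch and TGF-beta signalling 5 were higher and 3 lower (6 and 6 adjusted over the list alone; camera adjusted p = 0.540). The secreted glycoprotein gene Dkk3 rose from 77.5 ± 6.86 to 1279 ± 284 (3.78 ± 0.19), with Wnt4 (1.12 ± 0.22), Tgfb1 (1.30 ± 0.23), Tgfb3 (0.98 ± 0.17) and Notch1 (0.79 ± 0.17), while Tgfb2 (-1.03 ± 0.21), Fzd1 (-0.78 ± 0.14) and Jag1 fell. Of these, Dkk3 alone passed when cAMP replicate 1 was left out, and Dkk3 and Tgfb1 when cAMP replicate 2 was; without control replicate 1 the list counted 7 higher and 2 lower, with Jag1 lost, and without control replicate 2 6 and 6.

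No cell cycle gene passed. Among 35 tested, limma called 0, and 4 had an unadjusted p under 0.05: Cdk1 (-0.70 ± 0.23), Ccnb2 (-0.46 ± 0.18), Aurkb (-0.55 ± 0.21) and Kif23 (-0.58 ± 0.23). The share of changed genes was below that of the other genes, 1546 of 10000 (Fisher's exact test, adjusted p = 0.0105; camera adjusted p = 0.438). Of 20 interferon response genes, Oasl rose from 69.5 ± 59.8 to 462 ± 205 (2.62 ± 0.50) and 19 did not pass, with 1 higher adjusted over the list alone as well. Camera called the list higher (median 0.45, adjusted p = 0.0114, and adjusted p = 0.746 with an estimated correlation). All 20 were lowest on control replicate 2. Without that array the median was 0.019 with 1 gene higher and 1 lower, without control replicate 1 it was 0.95 with 17 higher, and without cAMP replicate 2 Oasl was lost.

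**Figure D3:**
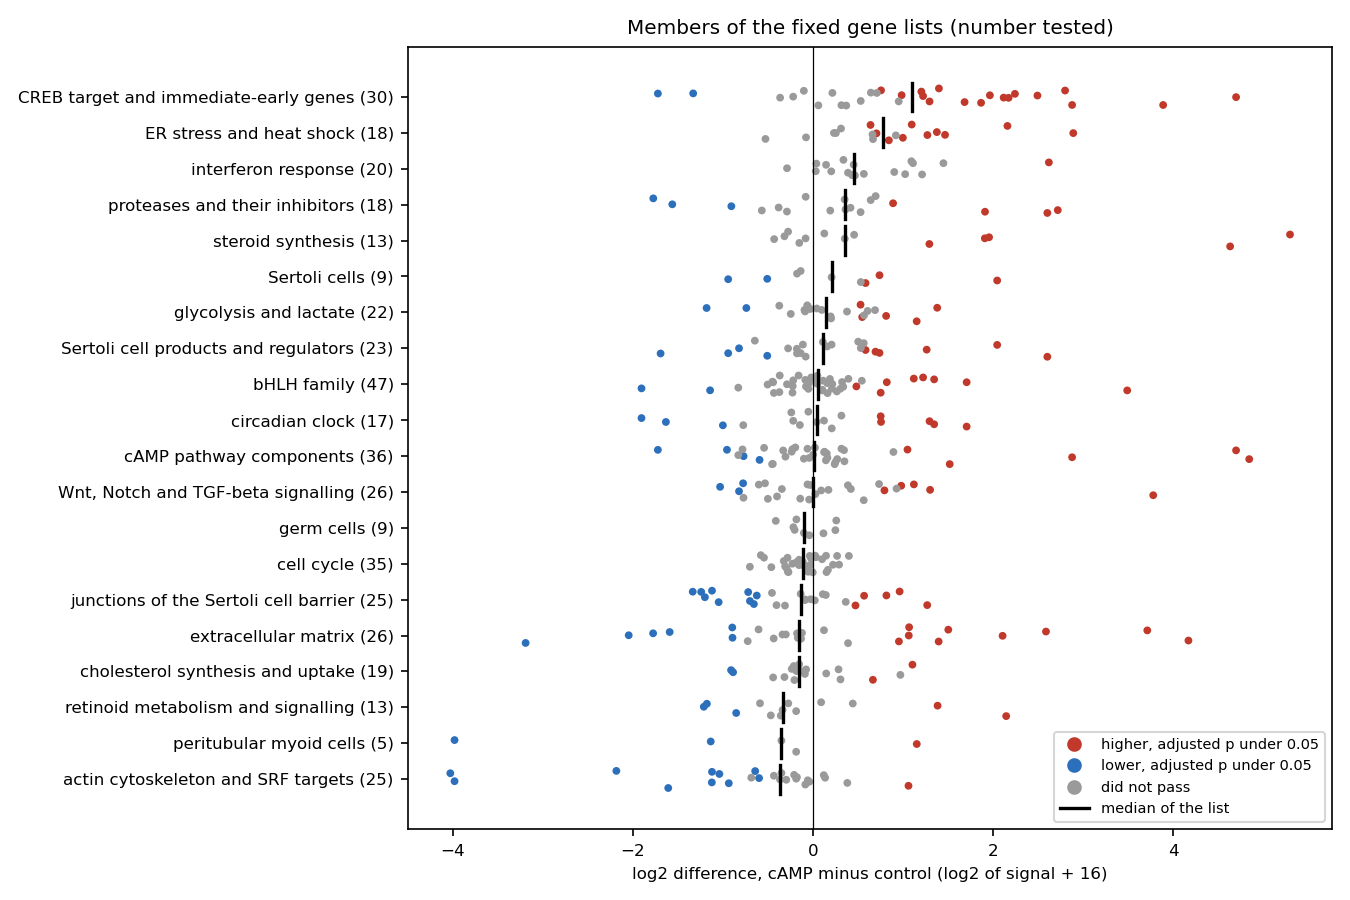
Log2 difference between cAMP and control, on the log2(signal + 16) scale, of each tested member of the 20 gene lists that camera tested (number of members in parentheses); colours show the direction of those past an adjusted p of 0.05, and black bars are list medians. The list of CREB target and immediate-early genes has the highest median, 1.09, and the actin list the lowest, -0.37.

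Transcripts of other testicular cell types were measured in the same arrays. Germ cell transcripts were present without passing the test: Sycp3, a protein of the meiotic chromosome axis, had signals of 2340 and 2298 on the control and 2258 and 1754 on the cAMP arrays (-0.22 ± 0.14), and Ldhc had a difference of -0.41 ± 0.23. Of the 9 germ cell genes tested limma called 0, and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.726). Of the Leydig cell markers, Star rose and Cyp11a1 did not pass, while Insl3, Lhcgr, Cyp17a1, Hsd3b1, Hsd17b3 and Hsd11b1 lay below the filter; Hsd11b1, at background on both control arrays and at least 2.78-fold higher with cAMP, passed the filter and was called higher without control replicate 1, without control replicate 2 and with a pseudocount of 64, which made 2 markers higher in each. Among markers of peritubular myoid cells, 5 of which were tested, Tagln and Synpo2 fell and the intermediate filament gene Des rose, while Myh11 (-0.35 ± 0.21) and Acta2 did not pass (camera adjusted p = 0.327, and 1 higher and 2 lower adjusted over the list alone). Synpo2 did not pass with a pseudocount of 64, without the filter on dim probe sets or without the intensity trend. Of the fibroblast markers Dcn and Fbln1 (1.39 ± 0.28) rose, Col1a1 (-0.12 ± 0.22) and Col1a2 (-0.61 ± 0.24) did not pass, and 4 lay below the filter. Of 17 leukocyte markers 13 lay below the filter; among the 4 tested limma called 0, with 1, Lyz2 (-1.05 ± 0.32), at an unadjusted p under 0.05. Of the endothelial markers Kdr fell by 1.23 on the log2 scale, 2 tested ones did not pass and 8 lay below the filter. Of the red cell markers Alas2 rose, and the globin gene Hbb lay below the filter. Synpo2, Des and Kdr were lost without cAMP replicate 1 and also without cAMP replicate 2, and Fbln1 in the first case; of the leukocyte markers 1 was higher and 2, with Lyz2, were lower without control replicate 1, and 1 was higher without control replicate 2.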

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

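The 2-fold minimum and the other alternatives given here were planned; leaving control replicate 2 out of the 3 lists written later, and Fisher's exact test, were chosen after the data had been seen. Without the filter on dim probe sets, 873 were higher and 725 lower in place of 1358 and 1191, and 6 bHLH genes changed in place of 10; more probe sets were then tested, 31042 in place of 18625. With a 2-fold minimum on the log2(signal + 16) scale 778 were higher and 583 lower. Leaving out each array in turn gave 396 to 2467 higher and 314 to 2381 lower probe sets and 4 to 13 changed bHLH genes. The lone array of a group was then assumed to vary like the other group's pair: counts were lowest without cAMP replicate 1 (396 and 314) or 2 (414 and 351), where only the more variable control pair sets the spread, and highest without control replicate 1. Without control replicate 2 they were 1446 and 1167.

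Of the 5 gene lists called by camera, 0 were called with an estimated correlation and 0 by fry's directional test. The cause was not tested for fry. With an estimated correlation, camera rests on the few residual degrees of freedom left by 2 arrays per group. Its adjusted p was 0.742 for many lists, among them the junction and bHLH lists, with estimated correlations of -0.034 and -0.014. That shared value is a tie made by the adjustment over the lists, not each list's own result. On so few degrees of freedom, camera with an estimated correlation cannot decide here whether a list shifted. The interferon list's median went from 0.45 to 0.019 without control replicate 2, where the direction given by camera turned, and leaving out each array in turn gave 0.019 to 0.95. It also lost its call without cAMP replicate 2, and the glycolysis list was called without control replicate 1. The other pseudocounts, normalizations, stricter filter and variance models kept the counts of higher and of lower probe sets and of changed bHLH genes within 1.5 times, 5 shifted lists in each, and between 50.7% and 55.8% of calls higher under every setting. Fisher's exact test, where not given above, passed for the CREB, stress, actin, protease and Sertoli marker lists. It did not pass for the steroid, cholesterol, cAMP pathway, glycolysis, retinoid, Wnt, interferon, germ cell and myoid lists. There its adjusted p lay between 0.0520 and 0.520.

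With the replicate number as a block 1540 were higher and 1495 lower, 10 bHLH genes changed, 7 higher, with Hif1a lost (adjusted p = 0.0502) and Tfap4 gained (adjusted p = 0.0391), and 5 lists shifted; Lyz2 (lower), Slc7a5 and Slc3a2 (higher) were called as well. The labels do not say that a number marks a shared batch, same-numbered arrays correlated by 0.163 in their deviations from the group means, and 2 pairs cannot show a pairing, so the numbers were taken as names. Of 203 genes followed, 77 were no longer past the threshold without cAMP replicate 1, 72 without cAMP replicate 2, 43 without the filter, 23 without the trend, 9 without control replicate 2, 6 without control replicate 1, 3 each with pseudocount 1 and quantile normalization, 2 with centring, 1 each with pseudocount 64 and the block, and 0 with robust eBayes. Some of the 203, such as Slc3a2, had not passed over all 4 arrays, so the lost share of those that had passed is larger. None of the 203 turned its direction past the threshold under these settings. Signals near or below background limit what can be said of dim genes.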

Other observations

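Of the tests here, those of fibroblasts, of the interferon genes and of Cyp11a1 were chosen after the result had been seen, as was leaving control replicate 2 out of the later lists. Those later lists were written after other genes of the same kind had been seen to change but before their members' values were, and without the genes that prompted them or other members already seen.

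The rises of Asns, Trib3 and Ddit4 prompted a list of 25 further genes that answer to ATF4, the transcription factor of the amino acid response. Of 23 tested, 11 rose and 12 did not pass, among them the amino acid transporter genes Slc38a2 (-0.05 ± 0.14), Slc7a5 (1.11 ± 0.30) and Slc3a2 (1.02 ± 0.28); the last pair passed without control replicate 1 and with each array centred on its median, Slc3a2 also without control replicate 2, and Slc7a5 also with a pseudocount of 64 and the filter at the 60th percentile. The mitochondrial folate enzyme gene Mthfd2 rose from 206 ± 18.2 to 1247 ± 23.8 (2.51 ± 0.14), the stress protein gene Nupr1 from 48.9 ± 9.19 to 495 ± 51.7 (2.98 ± 0.18), the cationic amino acid transporter gene Slc7a1 from 408 ± 110.1 to 1406 ± 165 (1.76 ± 0.20), and the serine synthesis genes Psat1 from 1062 ± 267 to 2984 ± 71.5 and Phgdh from 336 ± 149.6 to 1158 ± 164, the last lost without cAMP replicate 1. Camera gave p = 5.38e-11 (adjusted p = 1.61e-10 over the 3 later lists) at a median of 0.96, and p = 0.111 with an estimated correlation. Most of the 23 genes were lowest on control replicate 2, such as Phgdh, at 442 and 230.5 on control replicates 1 and 2. Without control replicate 2 the median was 0.65. A rise of part of the amino acid response is a hypothesis that may account for some of the change in the stress list. Both groups were cultured for 72 h. The design does not show whether cAMP acted on these genes directly or through a different use of the medium.

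The falls of Ccn2, Ankrd1 and Igfbp3 prompted a list of 23 further targets of the mechanosensitive cofactors YAP and TAZ. Of 19 tested, 9 fell, 9 did not pass and Dlc1 rose (1.15 ± 0.17, lost without cAMP replicate 1). Amotl2 fell from 1315 ± 4.17 to 375 ± 29.5 (-1.77 ± 0.13) and Ptpn14 from 469 ± 43.1 to 153 ± 7.78 (-1.52 ± 0.15), while F3 (-0.00 ± 0.22) did not pass. Camera gave p = 0.00146 (adjusted p = 0.00219) at a median of -0.50, and p = 0.0745 with an estimated correlation; without control replicate 2 the median was -0.59. Lower YAP and TAZ activity with cAMP may be a common thread of these genes and of the actin list, as a hypothesis. The last of these lists, 20 tested iron and haem genes prompted by the rises of Hamp, Lcn2, Scara5 and Alas2, which were left out of it, gave no shift (camera adjusted p = 0.553 over the 3 later lists). Slc11a2 (1.32 ± 0.12) and Slc39a14 (1.34 ± 0.17, lost without cAMP replicate 2) rose and Cp (-1.45 ± 0.20) fell. With members going both ways, a wider rise of iron handling cannot be told apart from changes of single genes.

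Star and Scarb1 were far higher with cAMP, and Leydig cells, which express both, are a candidate source. By the limit set beforehand, no other marker up by more than 1, a larger share of Leydig cells cannot be told apart from a response of the Sertoli cells, because Hsd11b1, a dim gene below the filter, lay at background without cAMP (3.5 and 2.7) and at 32 and 48.7 with it, at least 2.78-fold higher (1.54 on the log2 scale, where the control level is uncertain), and was called higher without control replicate 1, without control replicate 2 and with a pseudocount of 64. The 7 markers beside Star had a median difference of -0.00 with an SD of 0.66, and Cyp17a1, Hsd3b1, Insl3, Lhcgr and Hsd17b3 reached at most 24.3 on any array. In a later test, chosen after that result, the log2 difference of Cyp11a1 had an upper 95% bound of 0.59, where Star differed by 5.30. Cyp11a1 was dim, at 42.1 and 40.6 on the control and 50.9 and 42.4 on the cAMP arrays. The test argues only against a larger share of Leydig cells that express Cyp11a1. Whether Leydig cells already present raised Star was not tested. A response of the Sertoli cells themselves stays open as a hypothesis.

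Dcn, a proteoglycan abundant in fibroblasts, went from 1.9 and 17.1 to 465.5 and 381.7, and Fbln1, also on the fibroblast list, rose by 1.39 (lost without cAMP replicate 1), so that 2 of 4 tested markers were higher. More fibroblasts in the cAMP wells would bring fibrillar collagens with them. Yet the highest upper 95% bound among Col1a1, Col1a2 and Col3a1 was 0.47 on the log2 scale, with every signal of the 3 genes at or under 34.6. Col3a1 lay below the filter of the main fit, and these bounds are from another fit. The low bounds argue only against a larger share of fibroblasts that express these collagens. Whether fibroblasts already present raised Dcn, or changed their collagen expression with cAMP, was not tested. Fbln1 goes with more fibroblasts all the same, and cells that make Dcn and Fbln1 with little collagen, or induction of both in the Sertoli cells, stay open as hypotheses.

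The interferon list was called higher with cAMP, but its median was 0.019 without control replicate 2 and 0.95, with 17 of 20 genes higher, without control replicate 1. All 20 members were lowest on control replicate 2, with a median 1.07 below control replicate 1, while cAMP replicates 1 and 2 differed from control replicate 1 by medians of -0.13 and 0.10. With 2 controls, which of them stands apart is not known, so a rise caused by cAMP cannot be told apart from a low level in 1 control sample. A difference between cell preparations was not tested and stays open.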
